A study of Mus musculus with 19 samples.

How the data were processed

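The study measured RNA by sequencing in 19 libraries of mouse spleen myeloid cells, made from total RNA and read as 50 bp single-end reads, per the labels' protocols. The libraries fell into 4 groups by cell type and age: 6 of adult PMN-MDSC, 5 of newborn PMN-MDSC, 3 of adult M-MDSC and 5 of newborn M-MDSC. Groups, replicate numbers and batches were taken from the labels. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part.

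The authors deposited 1 table of estimated counts per gene, given as whole numbers and without normalization; the submitters' processing notes name RSEM version 1.2.3, the mouse build mm10 and, without a role, DESeq2. The aligner and the annotation release are not given in the sources used here. Rounding the estimated counts to whole numbers changed no value. The table held 38887 genes by Ensembl identifier, of which 852 had no symbol, and every measurement column was matched to 1 sample by its label. Estimated counts divide reads among related genes, so values of close paralogs are uncertain. The counting is not stated to use strand, so reads of a gene and of an antisense neighbour cannot be told apart. Gene coordinates came from GENCODE release M21 on GRCm38, the assembly also called mm10, by identifier; 37570 of the 38887 identifiers (96.6%) were in that release.

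Depth differed between batches. Total counts ran from 827744 to 2965896 in the 10 libraries of batch 1 and from 14026193 to 45135933 in the 9 libraries of batch 2. A count of 0 in 1 library allows a level of up to 3 counts, which was 0.990 to 3.29 CPM (counts relative to the scaled library size) in batch 1 and 0.0601 to 0.197 CPM in batch 2. Over a whole group the same 3 counts came to 0.0307 CPM in adult PMN-MDSC, 0.0435 in newborn PMN-MDSC, 0.139 in adult M-MDSC and 0.0577 in newborn M-MDSC. Where a group had no counts of a gene, its fold difference was computed against this floor over the group and is given as a lower bound. Where a group had 1 to 3 counts, the ratio is given with an exact 95% binomial interval. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

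Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 19 libraries entered 1 model with a coefficient for each group and for batch, after TMM scaling and edgeR's expression filter by group, which left 12943 genes and 14 residual degrees of freedom. Every adjusted p is a Benjamini-Hochberg value over the genes or lists of 1 comparison, and an adjusted p under 0.05 was called. The comparisons were newborn against adult within each cell type, the difference of these age effects between the cell types, and M-MDSC against PMN-MDSC within each age. Standard errors were derived from the fold change and the F statistic. Group levels are means of CPM with the SD over libraries.

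A set of 40 gene lists, 26 of pathways or processes and 14 of cell type markers, was fixed before the data were examined, from textbook knowledge. Several of them, including those of granule proteins and suppression genes, are known subjects of this study. The lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. Camera with an estimated correlation and the fry test were run beside it. Members were also adjusted over the list alone. Mean log2 CPM of marker lists was compared between ages by exact two-sided permutation tests within each cell type.

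The genes named were chosen by a rule fixed before the data were examined. For each age comparison it took the 8 largest called changes in each direction among genes of at least 10 CPM in the higher group, with the same sign in both batches and a symbol that is not a clone or predicted name. It added up to 4 members of each called pathway list and up to 2 of each list not called, by smallest adjusted p, and a fixed set of granule, suppression, cell division and sort genes. Genes of the fixed set are also given for the difference of the age effects, which the rule did not ask for. For the other comparisons it took the 5 largest in each direction, and Ly6g, Csf1r, Ccr2 and Camp for the cell types. Arg1 and Nos2 belonged to the fixed set and did not pass the expression filter. Not every gene the rule allowed is printed. Any other gene named is said to be chosen after its values were seen.

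The alternatives covered the batch term, a batch coefficient per cell type, fits on the compared groups only, single batches, a block of replicate numbers, DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, other expression filters, libraries scaled without haemoglobin, immunoglobulin and mitochondrially encoded genes, each library left out in turn and a 2-fold minimum. After the data were seen, 3 more were added: leaving out the batch 1 partners of matched libraries, treating matched libraries as a block, and leaving out a pair of M-MDSC libraries with few detected genes.

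The procedure was tested on simulated counts of 12943 genes drawn from the real mean levels, dispersions and library sizes. Of 100 genes changed 2-fold and 100 changed 4-fold, it called 35.0% and 55.0% for the age effect in PMN-MDSC, 21.0% and 57.0% for that in M-MDSC and 2.00% and 45.0% for their difference. For M-MDSC against PMN-MDSC it called 24.0% and 57.0% in adults and 31.0% and 65.0% in newborns. A cell division list raised 2-fold was called in all 5 simulated comparisons, with 0 of the 39 other lists. Genes and libraries were drawn independently, so the simulation cannot show how often correlated genes or libraries give false calls of lists or genes. Far fewer genes were changed than were called in the data, so the shares called need not hold there. Figures were drawn with matplotlib 3.10.9.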

Results

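Myeloid-derived suppressor cells (MDSC) are myeloid cells able to restrain T cell responses. Their neutrophil-like form, PMN-MDSC, carries CD11b and Ly6G with intermediate Ly6C, and their monocyte-like form, M-MDSC, carries CD11b and high Ly6C without Ly6G. Both were isolated from spleens of newborn mice (7 days old) and adult mice (6 to 8 weeks old), per the labels' protocols, which name CD11b and Ly6G beads and a cell sort. The study asked how these cells differ in newborns, a question its title ties to their passing accumulation after birth.

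Each group held libraries of both batches: 3 and 3 of adult PMN-MDSC, 2 and 3 of newborn PMN-MDSC, 2 and 1 of adult M-MDSC and 3 and 2 of newborn M-MDSC for batches 1 and 2. Total counts ranged from 827744 to 45135933 in adult and 2314868 to 39578510 in newborn PMN-MDSC. In M-MDSC they ranged from 1818926 to 16896783 in adults and 1785402 to 23344379 in newborns. In edgeR's model the batch term itself passed the threshold for 20 genes, 8 higher and 12 lower in batch 2.

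**Figure D1:**
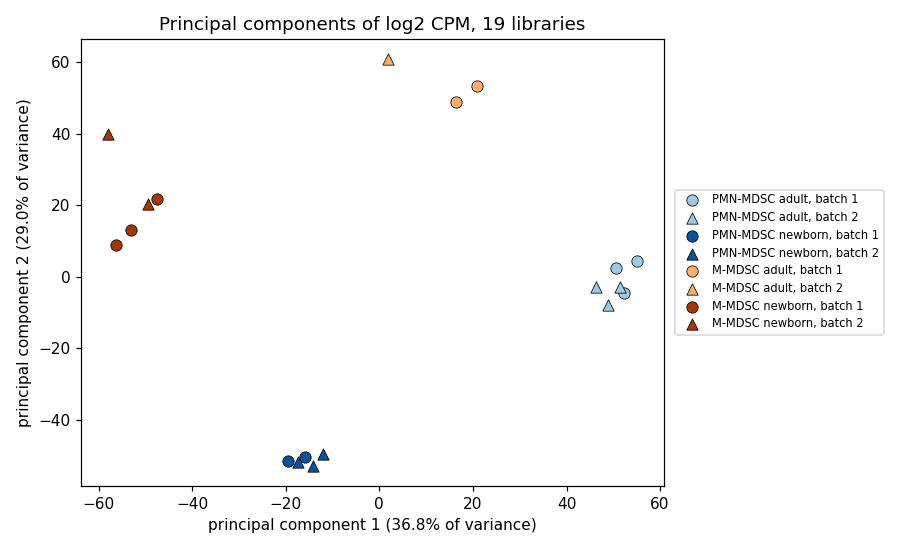
Position of the 19 libraries on the first and second principal components of log2 CPM of the 500 most variable genes, with colours for groups and symbols for batches. Component 1 held 36.8% of the variance and component 2 29.0%, and the libraries of each group lay together across batches, with adult PMN-MDSC at 46.3 to 55.2 and newborn M-MDSC at -58.1 to -47.5 on component 1.

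In PMN-MDSC, 5 pairs of libraries from different batches resembled each other more than the other pairs across batches did: adult replicates 1 and 32, 2 and 33, and 3 and 34, and newborn replicates 2 and 37, and 3 and 38. Their counts gave a chi-square per degree of freedom of 2.47 to 7.38, against 7.68 to 23.8 for the 10 other pairs across batches. The deviations of their genes from the mean of group and batch correlated at 0.326 to 0.512, against -0.359 to 0.127. These are correlations across genes, which are not independent replicates, and with 2 newborn libraries in batch 1 the values of 1 mirror those of the other. The pairs were chosen by their closeness. Within a batch, adult replicates 1 and 2 had a chi-square per degree of freedom of 5.80, against 7.38 for 2 and 33. These pairs differed in depth, so the values do not rank closeness. Treated as a block in limma-voom, matched libraries had a consensus correlation of 0.812. The share of immunoglobulin counts was also close within each pair. In adults it was 0.332% and 0.346%, 0.462% and 0.482%, and 0.577% and 0.595%. In newborns it was 0.0407% and 0.0422%, and 0.0515% and 0.0545%. The haemoglobin share of newborn replicate 2, 0.401%, was closer to the 0.371% of replicate 39 than to the 0.361% of its partner. The immunoglobulin values go with a shared source, but neither they nor the labels tell separate animals from preparations of 1 RNA for certain. If the matched libraries share a source, each PMN-MDSC group holds 3 sources, and the n of 6 and 5, the standard errors and the adjusted p below overstate the evidence. The libraries were entered as separate, and counts without the batch 1 partners stand beside the main ones below.

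The Y-linked gene Kdm5d had 0 counts in the 9 adult libraries and counts in all 10 newborn libraries, at 3.57 to 20.2 CPM in PMN-MDSC and 1.28 to 17.8 CPM in M-MDSC. Xist, the RNA of the inactive X chromosome, was present in all 19 libraries, at a pooled 1730.1 CPM in adult and 379.7 CPM in newborn PMN-MDSC. Other Y-linked genes had some counts in adults: Ddx3y had 39 in 3 PMN-MDSC libraries and 2 in 1 M-MDSC library, and Eif2s3y 45 in 4 PMN-MDSC libraries and 0 in M-MDSC. Uty had counts in all 9 adult libraries, at 1.44 to 3.60 CPM in PMN-MDSC and 1.10 to 2.08 CPM in M-MDSC, and was not called for age in either cell type (adjusted p = 0.156 and 0.121). By Kdm5d and Xist, age and the mix of sexes changed together between these groups.

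Newborn PMN-MDSC carried more RNA of neutrophil granule proteins than adult PMN-MDSC. Ltf, which encodes the iron-binding lactoferrin of secondary granules, averaged 29299 ± 2436 CPM in newborns (SD, n = 5) and 952 ± 182 CPM in adults (SD, n = 6), a log2 fold change of 4.96 ± 0.34 (SE; adjusted p = 1.19e-09) by edgeR's quasi-likelihood test. Camp, the cathelicidin antimicrobial peptide, rose from 193 ± 50.7 to 8201 ± 383 CPM, and Ngp, another secondary granule protein, from 494 ± 61.0 to 14294 ± 1691 CPM. S100a8, a subunit of the calcium-binding protein calprotectin, rose from 2499 ± 163 to 20176 ± 1774 CPM. Inflammatory genes went the other way: Il1b, the cytokine interleukin 1 beta, fell from 2213 ± 521 to 146 ± 32.7 CPM.

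By list, the secondary and tertiary granule genes rose together, since 20 of the 20 measured genes rose (20 adjusted over the list alone, median 4.11, adjusted p = 7.05e-15, adjusted p = 0.0706 with an estimated correlation). The largest rise in it was that of Olfm4, olfactomedin of a subset of neutrophils, with a log2 fold change of 7.08 ± 0.30 (SE; adjusted p = 4.23e-12). In the primary granule list, whose proteins are made at the promyelocyte stage, 6 of the 8 measured genes rose and 1 fell (6 and 1 adjusted over the list alone, median 3.77, adjusted p = 0.0332, adjusted p = 0.235 with an estimated correlation). On the log2 scale Mpo, the myeloperoxidase, rose by 4.57 and Elane, neutrophil elastase, by 3.43. Elane was at 4.43 (adjusted p = 5.16e-05) without adult replicate 34 and was not called in batch 1 alone, at 2.11 (adjusted p = 0.0596). Their newborn levels of 49.2 ± 7.32 and 10.5 ± 5.20 CPM stayed far below those of Ltf, Camp and Ngp. The summed level of the list did not rise, at 216 ± 25.4 CPM in newborns and 235 ± 41.7 CPM in adults. Ctsc, the protease that activates granule serine proteases, fell, at -1.38 (adjusted p = 5.31e-06). Of the granulocyte progenitor list, 10 of 20 genes rose (11 adjusted over the list alone) and 4 fell (median 1.90, adjusted p = 0.0201, adjusted p = 0.197 with an estimated correlation). Examples were Cebpe, the transcription factor of granule gene expression, at 5.70, and Fcnb, a ficolin, at 6.48. The neutrophil maturation list went both ways, with 8 genes higher and 8 lower (8 and 8 adjusted over the list alone), and was not called (median 0.39, camera adjusted p = 0.724). Among markers of neutrophils themselves, 10 of the 12 measured genes rose and 1 fell (10 and 1 adjusted over the list alone, median 3.18, adjusted p = 5.67e-05, adjusted p = 0.197 with an estimated correlation).

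Cell division genes were higher in newborn PMN-MDSC. Of the list of G2 and M phase genes, 35 of the 38 measured genes rose (35 adjusted over the list alone, median 3.16, adjusted p = 1.38e-13, adjusted p = 0.0736 with an estimated correlation). Members included Mki67, a proliferation marker, at 3.27 (adjusted p = 6.35e-06), Top2a, a topoisomerase, at 2.44, and Aurka, a mitotic kinase, at 3.43. Of the S phase list, 20 of the 34 measured genes rose and 1 fell (22 and 1 adjusted over the list alone, median 1.16, adjusted p = 6.41e-05, adjusted p = 0.197 with an estimated correlation). An example was the transcription factor E2f8 at 3.91. Energy metabolism genes were higher as well: 14 of 22 glycolysis and hypoxia genes rose and 4 fell (15 and 4 adjusted over the list alone, median 1.67, adjusted p = 0.00157, adjusted p = 0.201 with an estimated correlation). An example was the glucose transporter Slc2a3 at 1.76. For oxidative phosphorylation 24 of the 37 measured genes rose (24 adjusted over the list alone, median 0.72, adjusted p = 8.02e-04, adjusted p = 0.332 with an estimated correlation).

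Genes tied to suppression by MDSC moved in different directions, and their list was not called: 8 of 21 rose and 6 fell (8 and 7 adjusted over the list alone; median -0.15, camera adjusted p = 0.864). Subunits of the superoxide-producing NADPH oxidase rose, with Cybb at 2.94 ± 0.17 (SE; adjusted p = 1.23e-10) and Ncf1 at 2.77. In the oxidase list 7 of 8 genes rose (7 higher and 1 lower adjusted over the list alone, median 1.95, adjusted p = 1.05e-04, adjusted p = 0.0706 with an estimated correlation). The enzymes of prostaglandin E2 synthesis split: Ptges, the terminal synthase, rose from 2.03 ± 1.32 to 76.3 ± 5.57 CPM (log2 fold change 4.98, adjusted p = 5.92e-06), while Ptgs2, the inducible cyclooxygenase, fell from 365 ± 104 to 23.7 ± 5.14 CPM (log2 fold change -3.95, adjusted p = 5.88e-06). Lta4h, the leukotriene A4 hydrolase, rose by 4.29 on the log2 scale. The whole eicosanoid list had 9 higher and 6 lower of 19, the same adjusted over the list alone, and was not called (median 1.37, adjusted p = 0.208). Cd274, which encodes the checkpoint ligand PD-L1, fell, at -4.68 (adjusted p = 2.10e-05). Arg2, the mitochondrial arginase, was at -1.57 ± 0.66 (SE; adjusted p = 0.0561) and was not called. It was lower in newborns under every alternative, with adjusted p from 6.29e-07 to 0.154, and it was called without adult M-MDSC replicates 1 or 28 or newborn M-MDSC replicate 77, among other alternatives. Its levels of 29.6 to 47.5 CPM in the newborn libraries lay below the 78.6 to 157 CPM of the adult ones. Arg1 and Nos2, the arginase and nitric oxide synthase often used to mark MDSC, did not pass the expression filter. Arg1 had 9 counts in 2 of 5 newborn and 0 in the 6 adult PMN-MDSC libraries, and Nos2 had 11 counts in 2 newborn and 7 in 1 adult library.

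**Figure D2:**
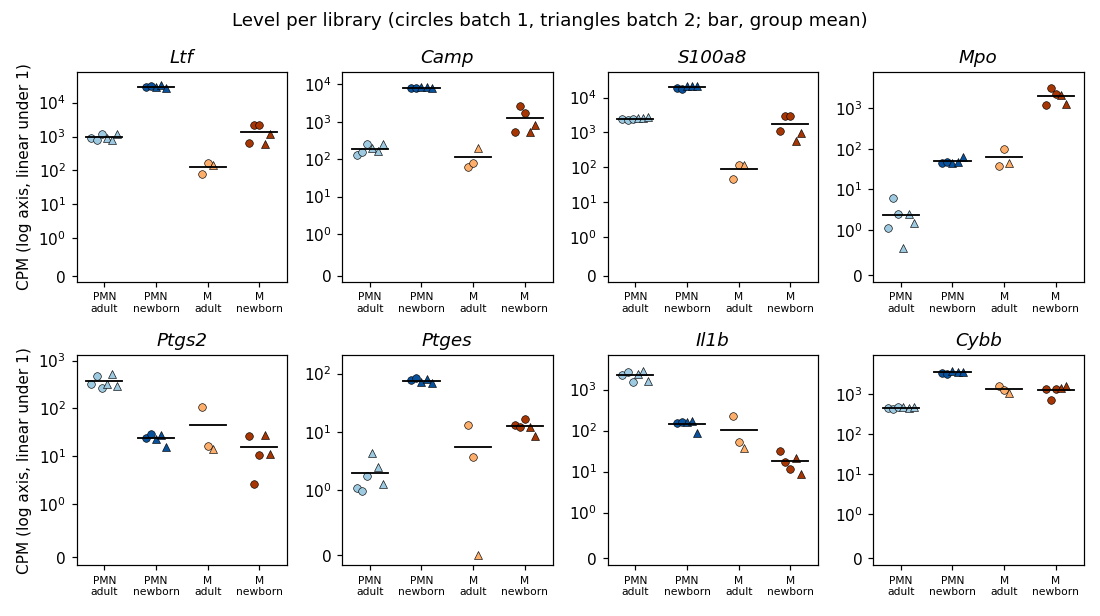
CPM of 8 genes in each of the 19 libraries, by group, on a log axis that is linear under 1 CPM; circles are batch 1, triangles batch 2 and bars group means. Ltf averaged 29299 CPM in newborn and 952 CPM in adult PMN-MDSC, while Mpo was highest in newborn M-MDSC, at a mean of 1981 CPM.

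Genes of inflammation and antigen presentation were lower in newborn PMN-MDSC. Among interferon response genes 31 of the 35 measured genes fell (32 adjusted over the list alone, median -2.75, adjusted p = 1.37e-11, adjusted p = 0.197 with an estimated correlation). Genes of this list were Oasl1 at -6.76, Oasl2 at -4.95 and Ifit3 at -5.61. Of the NF-kB list, 23 of the 27 measured genes fell and 1 rose (23 and 1 adjusted over the list alone, median -2.28, adjusted p = 3.93e-07, adjusted p = 0.278 with an estimated correlation). An example was Nfkb2 at -2.00. In the list of AP-1 and early response genes 18 of the 21 measured genes fell and 1 rose (18 and 1 adjusted over the list alone, median -1.54, adjusted p = 8.06e-07, adjusted p = 0.235 with an estimated correlation). An example was the stress factor Atf3 at -4.62. Chemokine and trafficking genes had 17 lower and 4 higher of 26, the same adjusted over the list alone (median -1.39, adjusted p = 0.00586, adjusted p = 0.197 with an estimated correlation). An example was the lymph node homing receptor Ccr7 at -4.61. Glucocorticoid-responsive genes had 9 lower and 3 higher of 15, the same adjusted over the list alone (median -1.86, adjusted p = 0.0393, adjusted p = 0.235 with an estimated correlation). An example was Tsc22d3 at -2.07. For MHC class I 12 of the 14 measured genes fell (12 adjusted over the list alone, median -0.82, adjusted p = 1.10e-05, adjusted p = 0.0706 with an estimated correlation). Genes of this list were H2-K1 at -1.69 and Nlrc5, the activator of this gene family, at -3.54. For MHC class II 15 of the 15 measured genes fell (15 adjusted over the list alone, median -2.78, adjusted p = 8.40e-10, adjusted p = 0.0736 with an estimated correlation). An example was H2-DMb1 at -2.78.

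Markers of other cells differed between the ages together with these groups. In the B cell list 13 of the 14 measured genes fell (14 adjusted over the list alone, median -2.93, adjusted p = 1.92e-08, adjusted p = 0.108 with an estimated correlation). The summed level of its 14 genes was 866 ± 154 CPM in newborns and 6259 ± 1227 CPM in adults. In the plasma cell list 7 of the 8 measured genes fell (7 adjusted over the list alone, median -3.01, adjusted p = 8.02e-04, adjusted p = 0.0706 with an estimated correlation). Immunoglobulin genes took 0.0508 ± 0.00984% of counts in newborn and 0.466 ± 0.111% in adult PMN-MDSC. T cell markers had 5 of 15 lower (1 adjusted over the list alone, median -1.56, adjusted p = 0.0332, adjusted p = 0.461 with an estimated correlation). NK cell markers had 3 of 8 lower (2 adjusted over the list alone, median -2.08, adjusted p = 0.0299, adjusted p = 0.278 with an estimated correlation), and dendritic cell markers had 5 of 12 lower (6 adjusted over the list alone, median -1.55, adjusted p = 0.0323, adjusted p = 0.284 with an estimated correlation). Erythroid markers went up, as 17 of the 19 measured genes rose (17 adjusted over the list alone, median 3.62, adjusted p = 4.67e-04, adjusted p = 0.367 with an estimated correlation), to a summed 4514 ± 1175 CPM from 296 ± 152 CPM. The sort genes rose in 3 of 4 cases, the same adjusted over the list alone (median 3.05, adjusted p = 0.00520, adjusted p = 0.0736 with an estimated correlation): Itgam, the gene of CD11b, at 2.70, Ly6g at 3.41 and Ly6c2 at 3.48. Their proteins were used to choose the cells.

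The largest single rises were those of eosinophil granule and stefin genes. Epx, eosinophil peroxidase, had 0 counts in the 6 adult libraries and averaged 111 ± 50.5 CPM in newborns, at least 3369.6-fold higher against the floor over the group, and the eosinophil-associated ribonucleases Ear6 and Ear1 were at least 1188-fold and 862-fold higher. Ear6 and Ear1, like the stefins Stfa1 (10.41), Stfa2 (10.35) and Stfa3 (12.72), belong to families of close copies among which estimated counts are uncertain. Tom1 was at least 188-fold higher, with an SD of 42.7 CPM around its mean of 21.7 CPM. Newborn replicate 2 carried most of that level, at 97.9 CPM, while 2 of the 5 newborn libraries had 0 counts, and the call was lost under 4 of 34 alternatives (adjusted p up to 0.576). Hist1h2al, a histone pseudogene, was at least 427-fold higher, a call lost with matched libraries as a block (adjusted p = 0.0589). The fetal RNA-binding gene Igf2bp3 rose by 3.91 and the transcription factor Arid3a by 2.88, in a list of fetal and neonatal genes that was not called (3 higher and 1 lower of 6 measured, the same adjusted over the list alone; median 1.78, adjusted p = 0.0873). Among the largest falls were those of Igha, the IgA heavy chain, with 1 count in newborns and 13461 in adults, a ratio of 9522-fold (95% counting interval 1709 to 376138), of Oasl1 (-6.76), of Irg1 (-6.22), which makes itaconate, and of the phosphatase Dusp4 (-6.19). On GRCm38, Ltf (ENSMUSG00000032496) is a protein-coding gene on chromosome 9 from 111019271 to 111042767, Camp (ENSMUSG00000038357) lies on chromosome 9 from 109847379 to 109849617, S100a8 (ENSMUSG00000056054) on chromosome 3 from 90668978 to 90670035 and Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139.

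In total, 6171 of 12943 genes passed the threshold in PMN-MDSC, 3514 higher and 2657 lower in newborns, of which 6167 (99.9%) had the same sign in both batches. By camera 23 of 40 lists were called, 11 up and 12 down. None was called with an estimated correlation, and fry called 36. Upper-quartile scaling gave 2756 genes higher and 3552 lower, and the DESeq2 Wald test 3168 and 3680. Relative to TMM, upper-quartile scaling and DESeq2 size factors moved the median of all genes by -0.24 and -0.17 on the log2 scale. Without the batch 1 partners of matched libraries 3740 genes were called, 2531 higher and 1209 lower, of which 3630 were among the 6171. The lists not mentioned above were not called. Medians and adjusted p in inflammation and metabolism were: pattern recognition (median -0.82, adjusted p = 0.143), ER stress (-0.36, 0.0935), cholesterol synthesis (0.14, 0.904), lipid uptake and storage (0.02, 0.431), complement and Fc-mediated phagocytosis (0.06, 0.124). For cell types they were: classical monocyte (0.90, 0.124), nonclassical monocyte (-1.04, 0.0543), monocyte (-0.58, 0.633), macrophage (-0.18, 0.316). For the remaining markers they were: platelet (0.43, 0.431), eosinophil, basophil and mast cell (-0.27, 0.421), stem and progenitor (1.67, 0.0935) and stroma (-0.22, 0.344). The medians of the cholesterol, lipid and complement lists changed sign under another scaling. In the suppression, maturation, monocyte and eosinophil lists the median, the mean and the direction of the test were not all of 1 sign.

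In M-MDSC the newborn cells were marked by RNA of primary granule proteins and of cell division. Mpo averaged 1981 ± 785 CPM in newborns (SD, n = 5) and 61.0 ± 33.6 CPM in adults (SD, n = 3), a log2 fold change of 5.06 ± 0.50 (SE; adjusted p = 6.42e-07) by edgeR's quasi-likelihood test, and Elane rose from 43.3 ± 18.6 to 855 ± 388 CPM. Cd74, the invariant chain of MHC class II, fell from 1958 ± 418 to 106 ± 70.8 CPM (log2 fold change -4.26, adjusted p = 1.83e-07). Mki67 rose by 3.25 and Top2a by 3.18 on the log2 scale. For Mki67 adult replicate 28 lay at 6.28 CPM against 81.2 and 83.8 CPM of the others, and without it the rise was 2.52 (adjusted p = 4.33e-05). The genes of the sort markers were not called: Itgam at 0.15 (adjusted p = 0.483), Ly6c2 at 0.44 (adjusted p = 0.242) and Ly6g, with 2 counts in the adult group, at a newborn mean of 0.877 ± 0.836 CPM (adjusted p = 0.143). Ly6g was called without adult replicate 3 or newborn replicate 77, with adjusted p from 0.00796 to 0.826 over the alternatives.

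Of the primary granule list, 6 of 8 genes rose (7 adjusted over the list alone, median 4.05, adjusted p = 2.35e-05, adjusted p = 0.0488 with an estimated correlation). Members included cathepsin G, Ctsg, at 5.92 (4.74 without adult replicate 28 and 10.53 without replicate 3), and proteinase 3, Prtn3, at 3.83. Of the secondary and tertiary granule list, 12 of the 20 measured genes rose (12 adjusted over the list alone, median 1.52, adjusted p = 4.83e-07, adjusted p = 0.122 with an estimated correlation). Among them were Olfm4 at 5.47, Lcn2 at 3.73, Ltf at 3.37 and Camp at 3.44. S100a8 rose from 92.0 ± 39.8 to 1709 ± 1156 CPM and S100a9 by 3.78. The size of these rises differed between batches: S100a9 rose by 4.83 (adjusted p = 7.60e-05) in batch 1 and 1.64 (adjusted p = 0.00975) in batch 2 alone, and Camp by 4.52 (adjusted p = 2.91e-04) and 1.82 (adjusted p = 0.00955). Without adult replicate 28 Camp rose by 4.20 (adjusted p = 4.60e-05) and Olfm4 by 6.79 (adjusted p = 3.10e-07). Neutrophil markers moved with these groups, since 9 of the 12 measured genes rose (9 adjusted over the list alone, median 2.96, adjusted p = 3.38e-06, adjusted p = 0.0997 with an estimated correlation). Their summed level was 7941 ± 5184 CPM in newborns and 903 ± 248 CPM in adults. Of the granulocyte progenitor list 12 of 20 genes rose and 3 fell, the same adjusted over the list alone (median 1.77, adjusted p = 3.43e-04, adjusted p = 0.0531 with an estimated correlation). An example was the growth factor receptor Kit at 3.70. Stem and progenitor markers had 5 of 9 higher (5 higher and 1 lower adjusted over the list alone, median 2.00, adjusted p = 0.0172, adjusted p = 0.0760 with an estimated correlation). In the fetal and neonatal list 3 of the 6 measured genes rose (3 adjusted over the list alone, median 1.36, adjusted p = 0.00791, adjusted p = 0.0531 with an estimated correlation). Genes of this list were Lin28a, a fetal regulator of let-7 processing, at 5.26 (adjusted p = 3.51e-05), which was 3.66 (adjusted p = 2.00e-04) without adult replicate 28 and 7.80 (adjusted p = 1.68e-06) without replicate 3, and Igf2bp3 at 4.53.

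Cell division lists rose nearly throughout in newborn M-MDSC. In the S phase list 29 of the 34 measured genes rose (31 adjusted over the list alone, median 2.94, adjusted p = 4.45e-22, adjusted p = 0.0115 with an estimated correlation). Examples were Mcm3, part of the replication helicase, at 2.92 and Uhrf1 at 4.15. In the list of G2 and M phases 37 of the 38 measured genes rose (38 adjusted over the list alone, median 3.61, adjusted p = 1.13e-26, adjusted p = 0.0122 with an estimated correlation). An example was Ccna2, cyclin A2, at 4.88. Glycolysis and hypoxia genes had 11 of 22 higher and 1 lower, the same adjusted over the list alone (median 0.65, adjusted p = 0.0146, adjusted p = 0.287 with an estimated correlation). For oxidative phosphorylation 13 of the 37 measured genes rose (15 adjusted over the list alone, median 0.57, adjusted p = 5.39e-04, adjusted p = 0.297 with an estimated correlation).

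Lower in newborn M-MDSC were interferon, antigen presentation and early response genes. In the interferon list 33 of the 35 measured genes fell (33 adjusted over the list alone, median -2.61, adjusted p = 1.70e-16, adjusted p = 0.0809 with an estimated correlation). An example was Oasl2 at -4.06. In MHC class I 12 of the 14 measured genes fell (12 adjusted over the list alone, median -1.48, adjusted p = 1.63e-09, adjusted p = 0.0115 with an estimated correlation). Called members included H2-K1 at -2.66 and Nlrc5 at -3.21. In MHC class II 12 of the 15 measured genes fell (12 adjusted over the list alone, median -1.96, adjusted p = 1.23e-09, adjusted p = 0.0531 with an estimated correlation). NF-kB genes had 18 of 27 lower (24 adjusted over the list alone, median -1.94, adjusted p = 8.29e-07, adjusted p = 0.282 with an estimated correlation). Genes of this list were Nfkb2 at -1.66 and Il1b at -2.41 (adjusted p = 7.05e-04). Adult replicate 1 had the highest Il1b, at 225 CPM against 52.3 and 36.7 CPM, and without it the change was -1.34 (adjusted p = 0.0132), and in batch 2 alone -1.25 (adjusted p = 0.120). Over the alternatives its adjusted p ran from 6.78e-07 to 0.120. Early response genes had 17 of 21 lower, the same adjusted over the list alone (median -1.54, adjusted p = 4.23e-08, adjusted p = 0.147 with an estimated correlation). An example was the heat shock gene Hspa1a at -4.31. Chemokine and trafficking genes had 12 lower and 2 higher of 26, the same adjusted over the list alone (median -0.68, adjusted p = 0.00207, adjusted p = 0.110 with an estimated correlation). An example was Ccr7 at -4.92. Glucocorticoid-responsive genes had 8 lower and 2 higher of 15, the same adjusted over the list alone (median -1.97, adjusted p = 0.00423, adjusted p = 0.104 with an estimated correlation). An example was Ddit4 at -4.31. Pattern recognition genes had 12 lower and 3 higher of 28, the same adjusted over the list alone (median -0.72, adjusted p = 0.0106, adjusted p = 0.319 with an estimated correlation). Complement and Fc-mediated phagocytosis had 8 lower (9 adjusted over the list alone) and 3 higher of 21 (median -0.84, adjusted p = 0.0459, adjusted p = 0.4999 with an estimated correlation).

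The nonclassical monocyte list, of the patrolling form of monocytes, had 13 of 19 genes lower (14 adjusted over the list alone, median -1.66, adjusted p = 1.41e-05, adjusted p = 0.112 with an estimated correlation). Called members included Ace at -3.35, which was -2.48 (adjusted p = 4.87e-06) without adult replicate 28, and Klf2 at -1.94. The classical monocyte list was not called, with 3 higher and 5 lower of 16 (4 and 5 adjusted over the list alone; median 0.09, adjusted p = 0.972). Beside these falls, markers of lymphocytes and other cells fell too: of the B cell list 13 of the 14 measured genes fell (13 adjusted over the list alone, median -3.93, adjusted p = 1.17e-11, adjusted p = 0.0531 with an estimated correlation). In the plasma cell list 7 of the 8 measured genes fell (7 adjusted over the list alone, median -4.23, adjusted p = 1.74e-05, adjusted p = 0.0115 with an estimated correlation). In the T cell list 13 of the 15 measured genes fell (13 adjusted over the list alone, median -3.84, adjusted p = 8.29e-07, adjusted p = 0.0997 with an estimated correlation). NK cell markers had 5 of 8 lower (5 adjusted over the list alone, median -3.82, adjusted p = 0.00350, adjusted p = 0.139 with an estimated correlation). Dendritic cell markers had 5 of 12 lower (5 adjusted over the list alone, median -2.14, adjusted p = 4.27e-04, adjusted p = 0.0997 with an estimated correlation), and macrophage markers 8 of 16 lower (9 adjusted over the list alone, median -0.89, adjusted p = 4.27e-04, adjusted p = 0.253 with an estimated correlation). Igha had 2 counts in newborns and 7160 in adults, a ratio of 8625-fold (95% counting interval 2387 to 71233). Among the largest rises, Cd63, a tetraspanin of granule membranes, had 0 adult counts and was at least 229.7-fold higher, Epx at least 138-fold, the mitotic genes Cdkn3, Cenpu and Mastl at least 103-fold, 87.0-fold and 100.4-fold, and the Y-linked Eif2s3y at least 239-fold. With limma-voom and quality weights the calls of Epx and Eif2s3y were lost, and that of Epx also with matched libraries as a block (adjusted p up to 0.271 and 0.251).

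The suppression list was not called in M-MDSC either, with 3 higher and 5 lower of 21, the same adjusted over the list alone (median -0.39, adjusted p = 0.446). Lta4h rose by 2.47 and Ptgs1, the constitutive cyclooxygenase, by 2.66, while Ptgs2 (log2 fold change -1.35, adjusted p = 0.0967), Ptges (log2 fold change 1.61, adjusted p = 0.175) and Cybb (log2 fold change -0.06, adjusted p = 0.846) were not called. Ptgs2 was at 0.12 (adjusted p = 0.907) without adult replicate 1 and was called without adult replicates 3 or 28 or newborn replicate 77, with adjusted p from 0.00681 to 0.907 over the alternatives. Arg2 and Cd274 were called lower, at -5.50 ± 1.49 (SE; adjusted p = 0.00907) and -2.59 ± 0.79 (SE; adjusted p = 0.0181), but without adult replicate 1 they were at -1.50 (adjusted p = 0.536) and -0.90 (adjusted p = 0.403). Irg1 likewise went from -7.66 (adjusted p = 0.00238) to -1.74 (adjusted p = 0.531), while Ptges went to 3.71 (adjusted p = 0.0118) and Ly6c2 to 0.87 (adjusted p = 0.0284). In batch 2 alone Arg2 and Cd274 had the other sign, at 2.36 (adjusted p = 0.594) and 1.38 (adjusted p = 0.235). Over the alternatives the adjusted p ran from 7.98e-05 to 0.728 for Arg2, 3.06e-04 to 0.894 for Cd274, 5.14e-07 to 0.996 for Irg1, 8.99e-04 to 0.451 for Ptges and 0.0284 to 0.673 for Ly6c2. Arg1 and Nos2 had 0 counts in the 8 M-MDSC libraries.

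Across all genes 3910 of 12943 were called in M-MDSC, 2054 higher and 1856 lower in newborns, of which 3708 (94.8%) had the same sign in both batches. By camera 26 of 40 lists were called, 10 up and 16 down, of which 5 were called with an estimated correlation: primary granule, S phase, G2 and M phases, MHC class I and plasma cell. A fit on the 8 M-MDSC libraries alone called 1267 genes, of which 1266 were among the 3910. Most of the 3910 calls were thus lost without the PMN-MDSC libraries. The main fit shared 1 estimate of spread per gene over all 19 libraries. The M-MDSC standard errors and adjusted p therefore rest in part on the spread between PMN-MDSC libraries, matched ones included. Not called were also eicosanoid synthesis (median 0.48, adjusted p = 0.0958), NADPH oxidase (0.45, 0.231), ER stress (-0.09, 0.425), cholesterol synthesis (-0.17, 0.261), lipid uptake and storage (0.05, 0.925). The same held for neutrophil maturation (0.12, 0.405), sort genes (0.81, 0.430), monocyte (0.09, 0.770). It also held for erythroid (1.74, 0.143), platelet (0.33, 0.874), eosinophil, basophil and mast cell (1.39, 0.139) and stroma (-0.88, 0.0887). The medians of the lipid and of both monocyte lists changed sign under another scaling. In these 3 lists and the platelet list the median, the mean and the direction of the test were not all of 1 sign. Replicates 28 of adult and 77 of newborn M-MDSC had counts for only 11549 and 11823 genes.

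**Figure D3:**
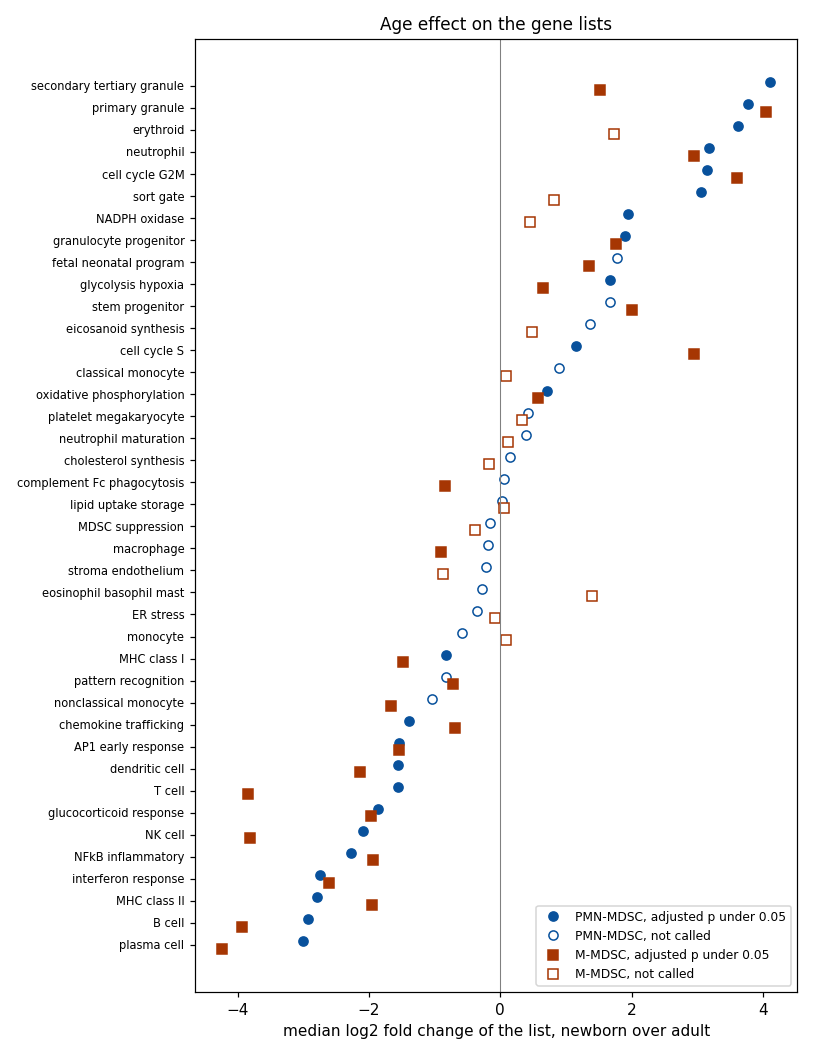
Median log2 fold change, newborn over adult, of the 40 fixed gene lists in PMN-MDSC (circles) and M-MDSC (squares), filled where camera with its preset correlation called the list. The secondary and tertiary granule list lay at 4.11 in PMN-MDSC and 1.52 in M-MDSC, and the S phase list at 1.16 and 2.94; the lipid list and both monocyte lists in M-MDSC and the cholesterol, lipid and complement lists in PMN-MDSC changed sign under another scaling.

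The age effects of the cell types overlapped. Of the genes called in both, 1470 were higher and 1097 lower in newborns of both cell types, where independent lists would share 557.7 and 381.0. Opposite calls were 100 genes higher in newborn PMN-MDSC and lower in newborn M-MDSC (503.9 for independent lists) and 59 the other way (421.7). Pearson's r of the fold changes was 0.585 across genes, which are not independent replicates, and the compared groups shared no library.

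A test of the difference asked where age acted differently in M-MDSC than in PMN-MDSC. The rise of the secondary and tertiary granule genes was smaller in M-MDSC. By the difference this list had 14 of 20 lower (15 adjusted over the list alone, median -1.73, adjusted p = 3.58e-11, adjusted p = 0.150 with an estimated correlation). The difference was -1.59 ± 0.47 (SE; adjusted p = 0.0225) on the log2 scale for Ltf, -1.97 for Camp and -1.69 for Ngp by edgeR's quasi-likelihood test. These calls depended on the libraries used. Without adult M-MDSC replicate 28 the difference was -1.39 (adjusted p = 0.0646) for Ltf, -1.23 (adjusted p = 0.151) for Camp and -1.40 (adjusted p = 0.107) for Ngp. Over the alternatives the adjusted p ran from 0.00693 to 0.345 for Ltf, 7.37e-04 to 0.504 for Camp and 0.00110 to 0.456 for Ngp, and the call was lost under 6, 6 and 14 of 34. NADPH oxidase genes were lower by the difference, at 7 of 8 lower (7 adjusted over the list alone, median -1.43, adjusted p = 1.86e-05, adjusted p = 0.0538 with an estimated correlation). In M-MDSC itself this list was not called for age. The difference for Cybb was -3.00 (adjusted p = 3.33e-07). S phase genes rose more in M-MDSC, at 13 of 34 higher (19 adjusted over the list alone, median 1.79, adjusted p = 2.98e-14, adjusted p = 0.0561 with an estimated correlation). The G2 and M phase list did so as well, at 5 of 38 higher (5 adjusted over the list alone, median 0.75, adjusted p = 5.40e-05, adjusted p = 0.668 with an estimated correlation). The difference was -3.37 (adjusted p = 0.0334) for Ptges and 2.60 (adjusted p = 0.0273) for Ptgs2, of which neither was called for age in M-MDSC. Both rested on few libraries: without adult M-MDSC replicate 1 they were -1.30 (adjusted p = 0.486) and 4.08 (adjusted p = 2.73e-04), and without replicate 28 -4.43 (adjusted p = 8.62e-05) and 2.03 (adjusted p = 0.0773). Over the alternatives their adjusted p ran from 8.62e-05 to 0.765 and from 2.73e-04 to 0.427, and Ptges changed sign in batch 2 alone and with matched libraries as a block. Itgam and Ly6c2, used to choose the cells, differed by -2.55 and -3.03, and the sort genes had 2 of 4 lower (2 adjusted over the list alone, median -1.62, adjusted p = 0.00661, adjusted p = 0.0997 with an estimated correlation). For S100a8, S100a9, Mpo, Elane, Il1b, Cd274, Arg2 and Mki67 the difference was not called, with adjusted p from 0.102 to 0.996. Without adult M-MDSC replicate 1 it was called for Cd274, at 3.78 (adjusted p = 0.0101), and Il1b, at 2.56 (adjusted p = 0.00136), without replicate 28 for Arg2, at -5.19 (adjusted p = 0.00386), and without newborn M-MDSC replicate 77 for S100a8, at 1.42 (adjusted p = 0.0403). Their adjusted p over the alternatives ran from 0.00470 to 0.620, 0.00136 to 0.493, 0.00386 to 1.00 and 0.0281 to 0.652. In batch 2 alone it was called for Mki67, at 3.45 (adjusted p = 0.00189), and for S100a9, at -1.24 (adjusted p = 0.0478). The sign of Arg2 also turned in batch 2 alone, at 3.90 (adjusted p = 0.402), and the value was 0.10 (adjusted p = 1.00) without adult M-MDSC replicate 1. In batch 2 alone S100a8 and Elane had the other sign as well, at -0.30 and -0.34. With the M-MDSC libraries of few detected genes left out the difference was called for S100a9 in the direction opposite to batch 2, at 1.72 (adjusted p = 0.0413).

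By the difference complement and phagocytosis genes had 9 of 21 lower (12 adjusted over the list alone, median -0.90, adjusted p = 5.32e-05, adjusted p = 0.502 with an estimated correlation). Classical monocyte genes had 2 higher and 6 lower of 16 (2 and 7 adjusted over the list alone, median -0.72, adjusted p = 0.0426, adjusted p = 0.502 with an estimated correlation). Nonclassical monocyte genes had 4 of 19 lower (6 adjusted over the list alone, median -0.76, adjusted p = 0.0408, adjusted p = 0.735 with an estimated correlation). T cell markers had 3 of 15 lower (7 adjusted over the list alone, median -2.33, adjusted p = 0.0119, adjusted p = 0.668 with an estimated correlation), macrophage markers 4 of 16 lower (6 adjusted over the list alone, median -0.86, adjusted p = 0.0427, adjusted p = 0.853 with an estimated correlation). The erythroid list was called down although none of its genes was, with 0 higher and 0 lower of 19, the same adjusted over the list alone (median -1.21, adjusted p = 0.0408, adjusted p = 0.853 with an estimated correlation). Among the single genes with the largest difference, Reck, a metalloprotease inhibitor, rose from 3.36 ± 1.55 to 59.0 ± 4.81 CPM in PMN-MDSC and went from 3.53 ± 2.34 to 1.89 ± 2.27 CPM in M-MDSC (log2 fold change -5.66, adjusted p = 5.75e-04). Nlrp12, a receptor that dampens inflammatory signalling, had 106 ± 20.3 and 107 ± 11.3 CPM in adult and newborn PMN-MDSC, 0 counts in adult M-MDSC and 4.43 ± 2.01 CPM in newborn M-MDSC (adjusted p = 5.84e-05). The call of Reck was lost in batch 1 alone and that of Nlrp12 with limma-voom and quality weights (adjusted p = 0.0715 and 0.0575). The difference was called for 2344 genes, 856 higher and 1488 lower, against 1157 and 1134 with upper-quartile scaling and 1441 and 1638 by the DESeq2 Wald test. It was called for 968 genes without the batch 1 partners of matched libraries, for 408 in batch 1 alone and for 4254 in batch 2 alone, where adult M-MDSC had 1 library. Upper-quartile scaling moved the median of all genes by 0.17. In 5 of 100 splits of the libraries that kept matched libraries together, the real one included, at least as many genes were called, up to 5582, so chance was not excluded for this count. Of the 4 other splits, 2 exchanged the ages of all PMN-MDSC libraries, which sums the age effects, and the highest without that gave 3224. By camera 11 of 40 lists were called, 2 up and 9 down, and 0 with an estimated correlation, while fry called 13. The lists not named here had adjusted p of 0.0532 to 1.00.

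Between cell types in adults, M-MDSC differed from PMN-MDSC by genes of monocytes. Fn1, fibronectin, averaged 2534 ± 717 CPM in M-MDSC (SD, n = 3) and 3.49 ± 0.908 CPM in PMN-MDSC (SD, n = 6), a log2 fold change of 9.42 ± 0.33 (SE; adjusted p = 1.01e-12) by edgeR's quasi-likelihood test. F13a1, a coagulation factor subunit, was higher by 8.78, the proteoglycan gene Vcan by 7.99, the chemokine receptor Ccr2 by 5.30 and Csf1r, the receptor of macrophage colony-stimulating factor, by 1.71. Ly6g had 2 counts in adult M-MDSC and 2155 in adult PMN-MDSC, a ratio of 238-fold (95% counting interval 65.9 to 1971). Nlrp12 had 0 counts in adult M-MDSC and was at least 815-fold lower, and the iron reductase gene Steap4, with 1 count, was lower by a ratio of 3061-fold (95% counting interval 549 to 120895). Camp was not called in adults, at -0.75 (adjusted p = 0.236), but it was without M-MDSC replicate 28, at -1.61 (adjusted p = 0.0432) (adjusted p from 0.0296 to 0.765 over the alternatives).

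Monocyte markers had 12 of 12 higher (12 adjusted over the list alone, median 3.62, adjusted p = 2.15e-14, adjusted p = 2.18e-04 with an estimated correlation). Classical monocyte genes had 11 higher and 1 lower of 16 (12 and 1 adjusted over the list alone, median 2.23, adjusted p = 2.47e-10, adjusted p = 0.00347 with an estimated correlation). Neutrophil markers had 11 of 12 lower (11 adjusted over the list alone, median -3.77, adjusted p = 1.96e-11, adjusted p = 0.0501 with an estimated correlation). Neutrophil maturation genes had 1 higher and 17 lower of 22 (1 and 18 adjusted over the list alone, median -3.15, adjusted p = 2.74e-11, adjusted p = 0.0581 with an estimated correlation). Primary granule genes had 6 of 8 higher (7 adjusted over the list alone, median 2.40, adjusted p = 2.10e-04, adjusted p = 0.0705 with an estimated correlation). MHC class I genes had 7 higher and 0 lower of 14 (8 and 1 adjusted over the list alone, median 0.52, adjusted p = 0.0172, adjusted p = 0.451 with an estimated correlation). ER stress genes had 8 higher and 3 lower of 22 (8 and 3 adjusted over the list alone, median 0.24, adjusted p = 0.0454, adjusted p = 0.555 with an estimated correlation). Oxidative phosphorylation genes had 14 of 37 higher (17 adjusted over the list alone, median 0.60, adjusted p = 7.37e-04, adjusted p = 0.464 with an estimated correlation). S phase genes had 1 higher and 8 lower of 34 (1 and 8 adjusted over the list alone, median -0.74, adjusted p = 0.00268, adjusted p = 0.451 with an estimated correlation). G2 and M phase genes had 1 higher and 7 lower of 38 (1 and 7 adjusted over the list alone, median -0.54, adjusted p = 0.0133, adjusted p = 0.670 with an estimated correlation). Of other cells, B cell markers had 11 of 14 lower (11 adjusted over the list alone, median -1.69, adjusted p = 3.88e-04, adjusted p = 0.451 with an estimated correlation) and macrophage markers 1 higher and 12 lower of 16 (1 and 13 adjusted over the list alone, median -1.92, adjusted p = 2.73e-04, adjusted p = 0.451 with an estimated correlation). In total 3772 genes were called, 2158 higher and 1614 lower in M-MDSC, against 2205 and 2582 by the DESeq2 Wald test. Without adult M-MDSC replicate 28, a library of few detected genes, 2250 genes were called, and without the batch 1 partners of matched PMN-MDSC libraries 2407. Camera called 12 of 40 lists, 6 in each direction, and with an estimated correlation the monocyte and classical monocyte lists. The 28 others had adjusted p of 0.0615 to 0.938.

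Genes of monocytes also parted the cell types in newborns. Fn1 averaged 7262 ± 982 CPM in M-MDSC and 24.7 ± 9.85 CPM in PMN-MDSC (SD, n = 5 and 5), a log2 fold change of 8.19 ± 0.33 (SE; adjusted p = 3.67e-12) by edgeR's quasi-likelihood test, and F13a1 was higher by 8.33, Ccr2 by 6.98 and Csf1r by 0.86 (adjusted p = 0.00411). Csf1r was not called in batch 2 alone, at 0.46 (adjusted p = 0.273), or without the batch 1 partners of matched libraries, at 0.69 (adjusted p = 0.109). Camp was lower in newborn M-MDSC, at -2.71 (adjusted p = 5.84e-05), and Ly6g at -8.18 (adjusted p = 9.46e-09). The receptor gene Mrgpra2a and the hyaluronan receptor gene Lyve1 had 0 counts in newborn M-MDSC and were at least 788-fold and 204-fold lower. Granule genes parted by kind. Primary granule genes had 7 of 8 higher (8 adjusted over the list alone, median 3.66, adjusted p = 2.00e-06, adjusted p = 0.0470 with an estimated correlation) in M-MDSC, while secondary and tertiary granule genes had 19 of 20 lower (19 adjusted over the list alone, median -3.49, adjusted p = 4.20e-12, adjusted p = 0.0889 with an estimated correlation).

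Among newborns, monocyte markers had 9 of 12 higher (10 adjusted over the list alone, median 4.63, adjusted p = 3.75e-10, adjusted p = 0.00178 with an estimated correlation) in M-MDSC. The classical monocyte list had 8 higher and 4 lower of 16 (9 and 4 adjusted over the list alone, median 0.89, adjusted p = 0.00256, adjusted p = 0.154 with an estimated correlation). The neutrophil list had 12 of 12 lower (12 adjusted over the list alone, median -4.23, adjusted p = 1.47e-10, adjusted p = 0.0659 with an estimated correlation), and the maturation list 1 higher and 20 lower of 22 (1 and 20 adjusted over the list alone, median -3.07, adjusted p = 6.68e-10, adjusted p = 0.0889 with an estimated correlation). The S phase list had 17 of 34 higher (19 adjusted over the list alone, median 0.90, adjusted p = 1.24e-06, adjusted p = 0.169 with an estimated correlation). The ER stress list had 11 higher and 1 lower of 22 (11 and 1 adjusted over the list alone, median 0.70, adjusted p = 7.98e-04, adjusted p = 0.264 with an estimated correlation), and oxidative phosphorylation 12 higher and 1 lower of 37 (12 and 1 adjusted over the list alone, median 0.42, adjusted p = 0.00179, adjusted p = 0.459 with an estimated correlation). The suppression list had 2 higher and 12 lower of 21 (2 and 12 adjusted over the list alone, median -1.29, adjusted p = 0.0133, adjusted p = 0.319 with an estimated correlation), with a median of -1.18 once a gene at 0 counts was put at its bound. The NADPH oxidase list had 6 of 8 lower (6 adjusted over the list alone, median -1.13, adjusted p = 0.00896, adjusted p = 0.163 with an estimated correlation). The complement and phagocytosis list had 3 higher and 15 lower of 21 (3 and 15 adjusted over the list alone, median -1.15, adjusted p = 0.00309, adjusted p = 0.440 with an estimated correlation). Markers of other cells moved too. The B cell list had 13 of 14 lower (13 adjusted over the list alone, median -2.23, adjusted p = 7.14e-05, adjusted p = 0.271 with an estimated correlation), the erythroid list 10 of 19 lower (11 adjusted over the list alone, median -2.68, adjusted p = 0.00184, adjusted p = 0.515 with an estimated correlation). The macrophage list had 1 higher and 14 lower of 16 (2 and 14 adjusted over the list alone, median -4.36, adjusted p = 4.19e-06, adjusted p = 0.213 with an estimated correlation), the platelet list 4 of 7 lower (4 adjusted over the list alone, median -2.03, adjusted p = 0.0418, adjusted p = 0.440 with an estimated correlation). The eosinophil, basophil and mast cell list had 4 of 9 lower (4 adjusted over the list alone, median -1.35, adjusted p = 0.0159, adjusted p = 0.213 with an estimated correlation). In total 5437 genes were called, 2414 higher and 3023 lower in M-MDSC, and 3231 in batch 1 alone. Upper-quartile scaling moved the median of all genes by 0.15. Camera called 17 of 40 lists, 6 up and 11 down, and with an estimated correlation the monocyte and primary granule lists. The 23 others had adjusted p of 0.0920 to 0.998.

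Of the genes called between cell types in both ages, 1110 were higher and 994 lower in M-MDSC at both ages, where independent lists would share 402.5 and 377.0, and 282 had opposite calls (805.1). The compared groups of the 2 ages shared no library.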

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

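Of the tests in this part, those of a larger share of every other cell type, of dilution by other cells, of carry-over of the average make-up and of the primary granule genes were chosen only after the result was seen.

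In some groups 1 library lay far from the others of its group on the log2 CPM scale. In newborn PMN-MDSC, replicate 39 had the highest Mpo, at 5.96 against 5.58 for the next library, and the lowest Il1b, at 6.48 against 7.25. In newborn M-MDSC, replicate 2 had the lowest Cybb, at 9.50 against 10.4, and replicate 77 the lowest mean of the MHC class I list, at 6.35 against 6.60. Of 90 such tests 4 gave an outlying library, and chance gives about 1 in 20.

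The age effect differed between the cell types (M-MDSC minus PMN-MDSC) for several genes and lists. For single genes it was -1.59 for Ltf (adjusted p = 0.0225), -1.97 for Camp (0.0284), -1.69 for Ngp (0.0397), 2.60 for Ptgs2 (0.0273) and -3.37 for Ptges (0.0334). It was -3.00 for Cybb (3.33e-07), and -2.55 for Itgam (8.70e-08) and -3.03 for Ly6c2 (1.30e-05), whose proteins were used to choose the cells. For lists the median difference was -1.73 for secondary and tertiary granules, -1.43 for NADPH oxidase, 1.79 for the S phase and 0.75 for the G2 and M phases. It was -0.72 for classical monocyte, -0.76 for nonclassical monocyte, -0.90 for complement and phagocytosis and -1.62 for sort genes. Of marker lists it was -1.21 for erythroid, -2.33 for T cell and -0.86 for macrophage. None of these lists was called with an estimated correlation. The values of single genes depend on adult M-MDSC libraries: without replicate 1 the difference was -1.30 (adjusted p = 0.486) for Ptges and 4.08 (adjusted p = 2.73e-04) for Ptgs2. Without replicate 28 it was -1.39 for Ltf (adjusted p = 0.0646), -1.23 for Camp (0.151), -1.40 for Ngp (0.107) and 2.03 for Ptgs2 (0.0773). The call was lost under 6 of 34 alternatives for Ltf and for Camp, 14 for Ngp and 10 each for Ptges, which also changed sign under 2, and Ptgs2. Their ranges of adjusted p over the alternatives are given above.

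Other splits into groups of the same sizes asked whether chance gives as many called genes. For age in PMN-MDSC 1 of 100 splits, the real one, reached 6171 genes, and the highest other gave 0. For age in M-MDSC 1 of 56 splits, the real one, reached 3910, and the highest other gave 929. For M-MDSC against PMN-MDSC 1 of 84 splits reached 3772 in adults, with 579 as the highest other, and 1 of 100 reached 5437 in newborns, with 13. For age in M-MDSC chance is excluded only if its libraries are independent, as matches were sought only across batches, in newborns. The other 3 take matched libraries as independent.

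Matched libraries may not be independent, so splits were repeated with them kept together. For age in PMN-MDSC and for the cell types in adults this leaves 10 splits, too few for a share under 0.05, with 6171 real against 0 and 3772 against 342. For the cell types in newborns 1 of 56 splits, the real one, reached 5437, and the highest other gave 2437. Chance is excluded there if the other libraries are independent.

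For the difference of the age effects 1 of 100 splits of the single libraries, the real one, reached 2344 genes, and the highest other gave 309. With matched libraries kept together, 5 of 100 splits reached it, the real one included, and the highest other gave 5582, so chance is not excluded. A first count, which left out part of the splits and gave a smaller share, was replaced after its result was seen. Of the 4 other splits, 2 exchanged the ages of all PMN-MDSC libraries, which sums the age effects, and the highest without that gave 3224.

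B cell, plasma cell and MHC class II genes were lower in newborn PMN-MDSC. A larger adult share of every other cell type was tested on erythroid genes alone, which rose in newborns (lower quartile log2 fold change 2.36). Lymphocyte and dendritic cell lists fell, and RNA of such cells in adults cannot be told apart from a change within the cells. Between the 3 adult libraries of batch 2, the median shifts of the B cell and MHC class II lists differed by at most 0.377, neither close enough nor far enough to decide. CD11b and Ly6G selection would remove B cells, yet adults held 6259 CPM of B cell and 10816 CPM of neutrophil markers. Age itself stays open.

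Secondary and tertiary granule genes were higher in newborn PMN-MDSC. Dilution of neutrophil RNA by other cells in the adult libraries cannot be decided. The upper quartile of the neutrophil maturation list, 1.23, lay below the lower quartile of the granule list, 3.30, while dilution alone would move both alike. A change of maturity with age could mask dilution in the maturation list, whose members went both ways. Summed neutrophil markers, at 107895 CPM in newborns and 10816 CPM in adults, and B cell markers, at 866 and 6259 CPM, go with dilution. A scaling set by a few abundant genes is argued against by the lowest median of the granule list over 4 scalings, 3.87. A change of maturity with age is consistent with these values, as a hypothesis found and tested on the same data. The mix of sexes, which changed with age, also stays open.

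Neutrophil granule genes were higher in newborn M-MDSC. If carry-over of newborn PMN-MDSC cells were the source, 55 genes abundant in these and low in adult M-MDSC should appear at 1 common share. The upper quartile of their shares was 3.41 times the lower quartile, which cannot be told apart from either case under the bounds set beforehand. Carry-over of cells of the average make-up is argued against: the 10th percentile of the shares was at most 0.214 of their median in each of the 5 libraries. Primary granule genes exceeded their level in newborn PMN-MDSC by a median log2 ratio of 3.66 (median absolute deviation 2.62), which carry-over cannot give, while less mature neutrophils or early progenitors may still contribute.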

How the results depend on the processing

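Leaving out the batch 1 partners of matched libraries, treating matched libraries as a block and leaving out the M-MDSC libraries with few detected genes were chosen only after the data were seen.

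Of the values of named genes under the alternatives, 5563 kept direction and side of the threshold, 99 kept direction but lost their call, 40 gained one, 32 moved and 7 reversed. Of list results 5098 stayed the same, 174 lost their call, 149 gained one, 178 moved and 1 reversed. Of marker means 25 stayed the same and 3 moved. The reversals were Arg2 in M-MDSC in batch 2 alone, at 2.36, Cd274 there at 1.38 and, with matched libraries as a block in limma-voom, at 0.21, and the lipid list between newborn cell types, down by the rotation test fry of limma (adjusted p = 0.00175). In batch 2 adult M-MDSC had 1 library, assumed to vary like the other groups. For the difference of the age effects, batch 2 alone reversed Ptges, at 6.12, S100a9, at -1.24, and Mki67, at 3.45, the values of S100a9 and Mki67 passed the threshold there, and the block reversed Ptges, at 0.67. Sign changes of values called in neither fit are counted as moved, among them Arg2 in the difference, at 3.90 in batch 2 alone and 0.28 with the block. For the reversals outside batch 2 the cause was not tested.

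Fitting only the compared groups called 9548 genes for age in PMN-MDSC and 1267 in M-MDSC, with 14479 and 10814 genes tested. Batch 1 alone, with fewer and shallower libraries, called 3760 for age in PMN-MDSC, 408 for the difference, 1368 between adult cell types and 3231 between newborn ones. Batch 2 alone called 4254 for the difference and 6457 between adult cell types. Limma-voom with quality weights called 2315 for age in M-MDSC and 1820 between adult cell types, and the cause was not tested. Without the batch 1 partners, with 14 libraries, 3740 genes were called for age in PMN-MDSC, 968 for the difference and 2407 between adult cell types. Asking for a 2-fold change left 4054, 2404 and 3552 genes for age in PMN-MDSC and the cell types in adults and newborns.

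Leaving out 1 library at a time gave 5459 to 7104 genes for age in PMN-MDSC, 3450 to 4340 in M-MDSC, 2021 to 2905 for the difference and 4777 to 6328 between newborn cell types. Between adult cell types it gave 2250, without M-MDSC replicate 28, to 5036, without replicate 1. Lists called ranged from 22 to 25, 25 to 27, 7 to 14, 12 to 15 and 16 to 17 for age in PMN-MDSC, age in M-MDSC, the difference and the cell types in adults and newborns. For the difference they fell to 7 without newborn PMN-MDSC replicate 38 or newborn M-MDSC replicates 77 or 79.

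An estimated correlation left 0, 5, 0, 2 and 2 lists called in the same order. The fry test called 36 for age in PMN-MDSC, 25 between adult and 27 between newborn cell types.

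A replicate block of the labels' numbers gave 6059, 3690, 2360, 3664 and 5068 genes in the same order of comparisons. Whether shared numbers mark paired samples stayed open. Deviations of the libraries of 1 number correlated at 0.176 and 0.182 between adult cell types, against at most 0.0292 for other numbers. They correlated at -0.0431 and -0.0220 for age in PMN-MDSC, 0.0672 and -0.00227 in M-MDSC, and -0.0472 and 0.00138 between newborn cell types. Depth limits the batch 1 libraries, where 3 counts come to 0.990 to 3.29 CPM.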

Other observations

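The test of the matched libraries below was chosen only after the result was seen.

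Some genes of eosinophil and basophil granules, chosen after their values were seen, were higher in newborns. Prg2, eosinophil major basic protein, averaged 301 ± 129.6 CPM in newborn and 0.418 ± 0.472 CPM in adult PMN-MDSC. In M-MDSC it averaged 80.5 ± 45.3 CPM in newborns and 0.617 ± 0.597 CPM in adults. Prss34, a basophil protease, rose from 0.982 ± 0.473 to 10.8 ± 2.47 CPM in PMN-MDSC, and in M-MDSC it had 0 counts in adults and averaged 5.64 ± 6.28 CPM in newborns. The list that holds these genes had 3 higher and 2 lower of 9 in PMN-MDSC (median -0.27) and 4 higher and 1 lower in M-MDSC. Its summed level was 829 ± 233 CPM in newborn and 873 ± 297 CPM in adult PMN-MDSC, and 152 ± 57.7 and 32.2 ± 4.19 CPM in M-MDSC. It was not called by camera in either cell type, at adjusted p of 0.421 and 0.139, while fry called it up in both, at 1.73e-05 and 1.76e-04.

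Some single genes of fetal cells and progenitors, again chosen after their values were seen, were higher in newborns, while in PMN-MDSC camera called neither the fetal list (adjusted p = 0.0873) nor the stem and progenitor list (adjusted p = 0.0935). Erg, a transcription factor of stem cells, averaged 119 ± 1.69 CPM in newborn and 3.09 ± 1.35 CPM in adult PMN-MDSC, with a log2 fold change of 5.30 ± 0.45 (SE; adjusted p = 2.06e-08). It was 5.09 ± 0.82 (SE; adjusted p = 1.28e-04) in M-MDSC. Lin28a averaged 208 ± 19.9 CPM in newborn and 10.9 ± 4.33 CPM in adult PMN-MDSC. Hmga2, another fetal gene, was not called in PMN-MDSC, at -0.28 (adjusted p = 0.812). The summed primary granule genes came to 4056 ± 1433 CPM in newborn M-MDSC and 216 ± 25.4 CPM in newborn PMN-MDSC, which was not above the 235 ± 41.7 CPM of adult PMN-MDSC.

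Matched PMN-MDSC libraries across batches may share a source or be alike but separate. Correlations of deviations, at least 0.326 in the 5 pairs and at most 0.127 in other pairs across batches, go with 1 source. So do immunoglobulin shares, but the pairs were chosen by their closeness. Centring also makes the values of the 2 newborn libraries of batch 1 mirror each other. The labels name no shared source. If there was 1, animals would be fewer than libraries.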
